A study of Mus musculus with 12 samples.

How the data were processed

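Total RNA of 12 cultures was hybridised to Affymetrix whole-transcript arrays after fragmentation and biotin labelling, per the labels' protocols. The cultures were 2TS22C ES cells and 22CEROH2-TSC1 TS cells, each untreated or given Tet at 1 ug/ml for 4 days, with 3 arrays per group. The values are the authors' log2 expression values, 1 per probe set and array, as deposited. Per the submitters' processing notes, Affymetrix Expression Console and the mm9 build were used. The background correction, normalization and summarization method are not given in the sources used here, so the scale was taken from the values themselves, which ran from 1.69 to 14.5 on the log2 scale. Array medians of 7.71 to 7.82 were close but not identical, and no detection p-values came with the values, so signal over background could not be judged for single probe sets.

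Genes were named from the array's platform annotation. Of 28946 probe sets, 18286 had 1 gene symbol, 1276 had several and 9384 had none. Only single-symbol probe sets were named. The gene IDs of 18097 of these matched a reference gene table (assembly GRCm38.p6), which changed 0 symbols. That assembly differs from mm9, so it served for names and neighbouring genes and no coordinates are given. For each gene the probe set with the highest mean over all 12 arrays was kept, which gave 17418 genes, 489 of them with more than 1 probe set. Of the 226 genes named by the rule below, 3 had more than 1 probe set, and 0 had another called probe set of opposite sign. Krt8, planned as a named gene, had no single-symbol probe set. Members of the fixed gene lists without a single-symbol probe set were left out of the counts.

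All 12 arrays were fitted in 1 model with a mean for each of the 4 groups using limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend; 8 residual degrees of freedom, prior degrees of freedom 2.52). Contrasts were ES Tet minus ES control, TS Tet minus TS control, the difference between these changes, and TS control minus ES control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and a 2-fold change is 1 on the log2 scale. All fold changes are differences of group means of log2 values. Duplicate arrays were sought, and any pair of arrays of a group shared at most 2 identical values, so all arrays were counted.

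The design, the main tests, the named-gene rule and 24 gene lists were fixed before the data were examined. The lists were ES cell pluripotency, trophoblast stem cell, trophectoderm and early trophoblast epithelium, trophoblast giant cell, spongiotrophoblast and syncytiotrophoblast, primitive endoderm, mesendoderm and primitive streak, neuroectoderm, postimplantation epiblast, germline, FGF-ERK feedback and targets, BMP-SMAD targets, other Sox family, mitosis, DNA replication, p53 targets, fibroblast (feeder) markers, epithelial junction, imprinted, interferon response, glycolysis and hypoxia, cholesterol synthesis, DNA methylation and Polycomb, and stress and immediate early genes. Lists overlap in some members, such as Eomes, Esrrb and Dab2. Each list with at least 5 measured genes was tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. With an estimated correlation, the calls that held were the pluripotency, spongiotrophoblast and syncytiotrophoblast, primitive endoderm and mesendoderm lists in ES cells and the primitive endoderm and mesendoderm lists in the difference between the lines. The self-contained test fry was an alternative. Named genes were the 10 largest rises and falls of the ES and TS responses and the 8 largest of the other comparisons among called genes whose groups did not overlap. Also named were up to 4 members of each list with the largest called changes and a fixed panel of Sox2 and stem cell genes. Names of the kinds Gm, Rik, LOC and ENSMUSG and of olfactory or vomeronasal receptors were passed over, except that all genes changed 2-fold in both lines are named. Sox2ot, Nodal and some other list members with opposite or telling directions were chosen after their values were seen.

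Alternatives were quantile normalization, median centring, cyclic loess, leaving out the dimmest 30% of genes, a trended and robust variance, fits of only the groups compared, the replicate number as a block, array weights, the mean of a gene's probe sets, all probe sets, limma's treat against a fold of 1.2, and leaving out each array. Cyclic loess, the list tests under other scalings and some alternatives for shared calls were chosen after the data were seen. The steps were tested on simulated arrays with known changes, drawn from the ES control means and the real spread. Each size of change was given to 66 or 67 genes, far fewer than were called in the data, so the shares below hold for that setting only. In the simulated ES response with 17418 genes, 83.3% of genes changed by 0.5 (log2), 97.0% of those changed by 1 and 97.0% of those changed by 2 were recovered, and 6.09% of calls were false. For the simulated difference between the lines, 59.1% of genes changed by 0.5 were recovered. The highest share of false calls was 7.32%, in the simulated comparison of the untreated lines. Figures were drawn with matplotlib 3.10.9.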

Results

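Gene expression was measured on 12 Affymetrix whole-transcript arrays in a mouse embryonic stem (ES) cell line and a trophoblast stem (TS) cell line, both of 129/Ola origin. In the ES line, 2TS22C, a Sox2 knockout can be induced with Tet, taken here as tetracycline, and the TS line, 22CEROH2-TSC1, was derived from it. Sox2 is a transcription factor that sustains pluripotency in ES cells and is also needed by trophoblast stem cells, which give rise to the placental trophoblast. Each line was grown with and without 1 ug/ml Tet for 4 days, with 3 arrays per condition and 4 groups in all. ES cells were grown with LIF at 1000 U/ml and TS cells with FGF4 at 50 ng/ml, heparin at 2 ug/ml and Activin A at 10 ng/ml, both in 10% serum. The sample labels place all cultures on embryonic fibroblast feeders and do not mention removal of the feeders before RNA extraction, while the growth protocol names gelatin-coated dishes for ES cells. Replicates are called biological in the labels, which do not say how the cultures were kept apart, so p-values measure the spread between these arrays. Array medians over all probe sets ran from 7.71 to 7.82 on the log2 scale, and arrays of a group correlated at r = 0.9955 to 0.997 across the genes tested. The number of arrays, 3 per group, limits the precision of every comparison.

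The targeted gene was examined first. The Sox2 probe set read 8.32, 8.29 and 8.47 (log2) in ES control replicates 1 to 3, and 8.76, 8.78 and 8.46 in the ES arrays labelled Tet. The group means were 8.36 ± 0.10 and 8.67 ± 0.18 (SD, n = 3 arrays each), a difference of 0.31 ± 0.12 (SE) that did not pass limma's test after Benjamini-Hochberg adjustment (adjusted p = 0.0809). In TS cells the same probe set read 7.14, 7.31 and 7.05 without Tet and 6.59, 6.47 and 6.91 with Tet, a change of -0.51 ± 0.12 (SE; limma adjusted p = 0.0167). The TS call was lost in the fits without TS control replicate 2, TS Tet replicate 1 or TS Tet replicate 2, where the adjusted p reached 0.0619. Sox2ot, a long noncoding gene whose locus overlaps Sox2, changed by 0.53 in ES cells (limma adjusted p = 0.00265) and by -0.50 in TS cells (limma adjusted p = 0.00666). In TS cells the Sox2 probe set read low, at percentiles 32 to 36 of genes without Tet and 22 to 29 with Tet. The parts of Sox2 read by the probe set and the construct by which Tet removes Sox2 are not given in the sources used here. The fall in TS cells thus does not show by itself that Tet removed Sox2 there. Nor can the Sox2 value check the Tet label of the ES arrays. Directions given for ES cells are therefore those of the ES arrays labelled Tet against the ES control arrays.

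**Figure D1:**
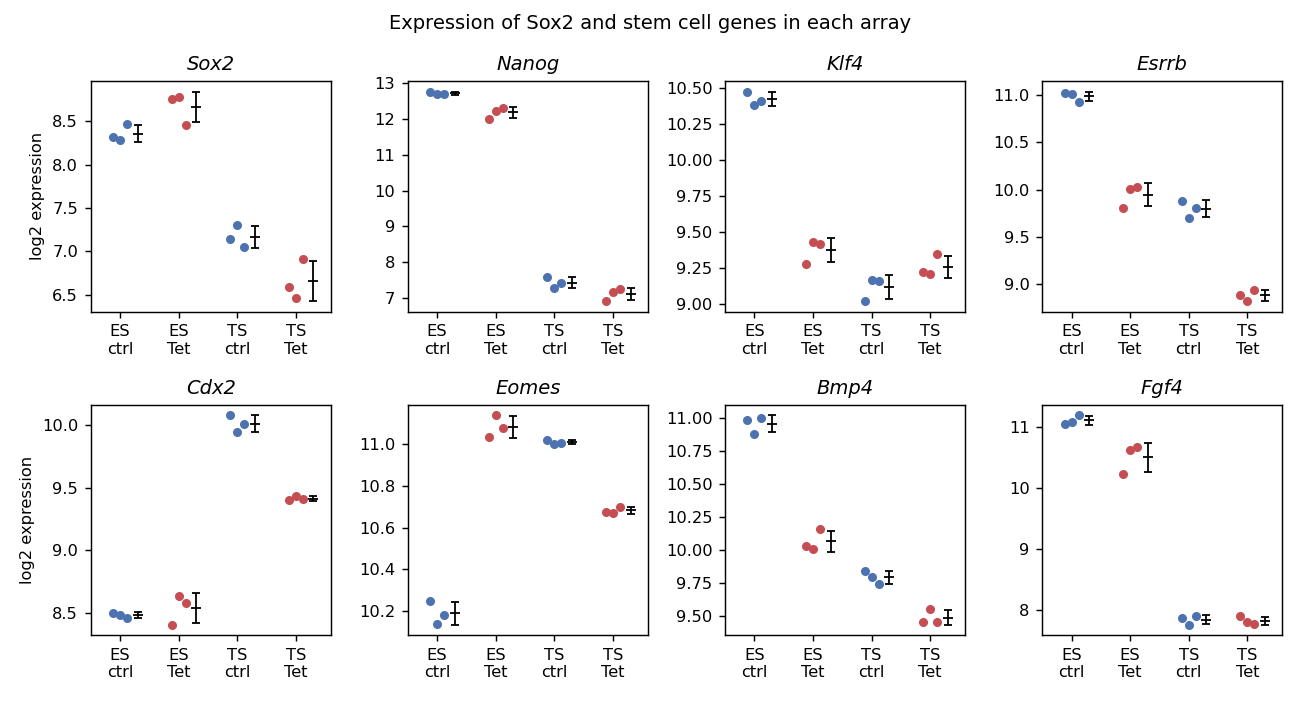
Log2 expression (y axis, a separate range for each gene) of Sox2 and 7 other stem cell genes in ES and TS cells without Tet (blue) and with Tet (red), with 1 point per array and the group mean and SD (n = 3) drawn beside the points. The Sox2 probe set read lower with Tet in TS cells (6.66 against 7.17) and not in the ES arrays labelled Tet (8.67 against 8.36). Which part of Sox2 it reads is not known. Klf4 and Fgf4 were lower in the ES arrays labelled Tet, and Cdx2 was lower in TS cells with Tet.

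The first comparison asked what changed in ES cells when the Sox2 knockout was induced for 4 days. In the ES arrays labelled Tet, most measured pluripotency genes were lower and most measured primitive streak genes were higher, while lists of trophoblast genes differed in their results. The steepest falls were those of Necab1, a calcium-binding protein (8.57-fold lower; -3.10 ± 0.08 SE on the log2 scale), Lix1 (-2.73 ± 0.08) and Nr5a2, a nuclear receptor that can drive Pou5f1 (-2.15 ± 0.07). The steepest rises were those of Gjb2, a gap junction connexin (6.05-fold higher; 2.60 ± 0.09), Aplnr, the apelin receptor of early mesoderm (2.23 ± 0.07), and Cyp26a1, which degrades retinoic acid (2.18 ± 0.05). Necab1 ended at 6.22, a level also read in TS cells (6.20 without and 6.17 with Tet), so its fold is a minimum if this level is background. Each of these 6 genes had limma adjusted p values of 2.72e-08 or lower. The keratins Krt19 (8.54 ± 0.14 to 10.53 ± 0.05, mean ± SD, n = 3) and Krt18 (9.58 ± 0.04 to 11.56 ± 0.04) rose by 2.00 and 1.98, and Bmp5, Plac1, Klhl4 and the homeobox gene Lhx1 rose by 1.86 to 1.92. Among the further large falls were the nuclear receptor Nr0b1 (-1.66), the laminin chain Lama1 (-1.63), Cpsf4l (-1.62), Cpn1 (-1.60), the peptidase Dpp4 (-1.58), Cnpy1 (-1.57) and the sialyltransferase St8sia6 (-1.57), with limma adjusted p values of 0.00013 or lower.

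In all, 5485 of 17418 genes were called in ES cells, 3331 higher and 2154 lower (limma, adjusted p under 0.05), of which 88 rose and 82 fell by at least 2-fold. The balance of directions depended on the scaling of the arrays: centred on each array's median, 2340 genes were higher and 4124 lower, and 72 and 91 by at least 2-fold. Over all probe sets, with or without a gene symbol, 259 rose and 106 fell by at least 2-fold. Tested against a 1.2-fold minimum with limma's treat, 831 genes passed.

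Of the 28 measured genes of the ES cell pluripotency list, 21 were lower, 2 were higher and 5 did not pass the test. Its median was -0.59 (camera adjusted p = 7.10e-12; adjusted p = 0.0327 with an estimated correlation). Adjusted over the list alone, 21 were lower and 3 higher. Tbx3 (-1.50), Tcl1 (-1.47), Klf4 (-1.05; 2.07-fold) and Esrrb (-1.04) were lower. The highly expressed Nanog (12.71 ± 0.04 to 12.18 ± 0.16) and Pou5f1 (12.06 ± 0.04 to 11.67 ± 0.10) fell by 0.54 and 0.40. The Pou5f1 call was lost in the fits without ES control replicate 1 or 2 or ES Tet replicate 1 or 2. Fgf4, a growth factor made by ES cells, fell by 0.60, and Lefty1 and Nodal, both of the Nodal pathway, were the 2 list members that rose (by 0.45 and 0.56).

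Among the 16 measured genes of the mesendoderm and primitive streak list, 10 were higher and 1 lower. The list median was 0.68 (camera adjusted p = 2.86e-07; adjusted p = 0.0283 with an estimated correlation; 11 higher and 1 lower adjusted over the list alone). Cer1, a secreted Nodal antagonist, rose by 1.95, Lhx1 by 1.86, Mixl1 by 1.47 and the T-box gene Eomes by 0.89. Of the 11 measured genes of the postimplantation epiblast list, 7 were higher and 1 lower, both over all genes and adjusted over the list alone. The median was 0.58 (camera adjusted p = 0.00316; adjusted p = 0.0700 with an estimated correlation). Fgf5 rose by 1.25, Cdh2 by 0.87, Cldn6 by 0.80 and Lef1 by 0.62. The primitive endoderm list moved down, with 13 of 19 members lower, 3 higher and a median of -0.37 (camera adjusted p = 1.11e-07; adjusted p = 0.0283 with an estimated correlation; 14 lower and 3 higher adjusted over the list alone). Lama1, Cubn (-1.45) and Gata6 (-1.15) were lower, whereas Foxa2 rose by 1.12 and Sox17 by 0.61, 2 genes that also mark definitive endoderm.

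The trophectoderm and early trophoblast epithelium list had 10 of 15 members higher and 3 lower (10 and 4 adjusted over the list alone). Its median was 0.57 (camera adjusted p = 0.00279; adjusted p = 0.372 with an estimated correlation). Besides the keratins, Gata2 rose by over 2-fold and Gata3 by 0.63, and Tfap2a fell by 1.13. In the spongiotrophoblast and syncytiotrophoblast list, 8 of 14 members were higher and 1 lower, the same as adjusted over the list alone. The list median was 0.37 (camera adjusted p = 0.000598; adjusted p = 0.0283 with an estimated correlation). Gjb2, the placental kinase Nrk (1.44), the VEGF receptor Flt1 (1.28) and the lactate carrier Slc16a1 (0.84) were higher. Epithelial junction genes were higher in 14 of 15 cases and lower in 0, adjusted over the list alone as well. The median was 0.46 (camera adjusted p = 4.71e-09; adjusted p = 0.117 with an estimated correlation). The desmosome genes Dsp and Dsc2 rose by 1.40 and 1.34, and the claudin Cldn4 by 0.86. Of 14 measured trophoblast stem cell genes, 4 were higher and 5 lower (5 and 5 adjusted over the list alone; camera adjusted p = 0.459): Eomes rose, Sox21 (-1.16), Esrrb and Bmp4 (-0.89) fell, and Cdx2 (0.06) and Elf5 (-0.03) did not pass the test.

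Fibroblast markers, which are read in feeder cells, were lower in 11 of 23 cases and higher in 2, adjusted over the list alone as well. The median was -0.16 (camera adjusted p = 0.00211; adjusted p = 0.499 with an estimated correlation). Fbln2 (-0.43) and Col6a2 (-0.31) were lower and Tagln (0.49) and Twist1 (0.32) higher. The interferon response list had 5 of 11 members higher and 1 lower (7 and 1 adjusted over the list alone), led by Gbp2, Rsad2 (1.05) and Oasl2 (0.91). Its median was 0.25 (camera adjusted p = 0.00625; adjusted p = 0.372 with an estimated correlation). Cholesterol synthesis genes were higher in 6 of 14 cases and lower in 0, adjusted over the list alone as well. The list median was 0.09 (camera adjusted p = 0.0133; adjusted p = 0.413 with an estimated correlation), and the list call was lost after cyclic loess (adjusted p = 0.0840). In the DNA methylation and Polycomb list, 7 of 16 members were lower and 2 higher (7 and 3 adjusted over the list alone). The median was -0.04 (camera adjusted p = 0.0395; adjusted p = 0.580 with an estimated correlation). Tet2, which oxidises methylated cytosine, fell by 1.47 and Dnmt3l by 1.10. That list call was lost without ES control replicate 2, ES Tet replicate 2 or ES Tet replicate 3 (adjusted p up to 0.0633). Other Sox genes were lower in 6 of 18 cases and higher in 4 (7 and 4 adjusted over the list alone). The median was -0.12 (camera adjusted p = 0.0249; adjusted p = 0.378 with an estimated correlation), a call lost with median centring or without ES control replicate 3 (adjusted p up to 0.0803). Sox21, Sox7 and Sox15 (-0.60) fell, and Sox3 (-0.17, limma adjusted p = 0.143) did not pass the test.

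The remaining 11 lists did not pass the camera test in ES cells. FGF-ERK feedback genes had 1 member higher and 4 lower of 15 (median -0.04, camera adjusted p = 0.11; past the test in 3 of 11 alternatives, with adjusted p down to 0.0103), with Spry4 at -0.69 and Etv4 at -0.51. p53 targets had 6 higher and 0 lower of 16 (median 0.07, camera adjusted p = 0.119). Imprinted genes had 7 higher and 4 lower of 17 (median 0.16, camera adjusted p = 0.155). Stress and immediate early genes had 6 higher and 1 lower of 14 (median 0.07, camera adjusted p = 0.222), and neuroectoderm genes 3 higher and 4 lower of 14 (median -0.13, camera adjusted p = 0.290). Glycolysis and hypoxia genes had 4 higher and 5 lower of 16 (camera adjusted p = 0.416), and BMP-SMAD targets 5 higher and 4 lower of 12 (camera adjusted p = 0.999). Mitosis genes had 0 higher and 1 lower of 19 (median 0.04, camera adjusted p = 0.894), and DNA replication genes 4 higher and 3 lower of 18 (median 0.01, camera adjusted p = 0.914). Trophoblast giant cell genes had 1 higher, Hand1 at 0.78, and 0 lower of 13 (median -0.06, mean 0.01, camera adjusted p = 0.937). Germline genes had 2 higher and 3 lower of 14 (median 0.09, mean -0.04, camera adjusted p = 0.970). For the last 3 lists the sign of the camera test differed from that of the median or the mean.

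The second comparison asked the same of TS cells. With Tet, TS cells had lower levels of their own stem cell regulators Cdx2, Eomes and Esrrb and of genes for mitosis and DNA replication, and higher levels of several trophoblast genes. Cdx2 fell from 10.01 ± 0.07 to 9.41 ± 0.02 (mean ± SD, n = 3; 1.51-fold), Esrrb from 9.80 ± 0.09 to 8.88 ± 0.06 (1.88-fold) and Eomes from 11.01 ± 0.01 to 10.68 ± 0.02 (1.25-fold). The largest falls were those of the peptidase gene Cpm (3.83-fold; -1.94 ± 0.04 SE), the cadherin Cdh6 (-1.93 ± 0.06), the peptidase gene Mme (-1.72 ± 0.06) and Tm6sf1 (-1.71 ± 0.10). The largest rises were those of the orphan receptor Gpr50 (3.58-fold; 1.84 ± 0.10), the transglutaminase Tgm2 (1.64 ± 0.08) and the phosphate carrier Slc34a2 (1.44 ± 0.07), and these 7 genes had limma adjusted p values of 2.17e-06 or lower. Zfp36l3, an RNA-binding protein of the rodent placenta, rose by 1.37, Nrk by 1.36, the prostaglandin carrier Slco2a1 by 1.30, Gbp2 by 1.29, the germline factor Taf7l by 1.29 and Serpinb9c by 1.27. EG622494 also rose, by 1.37 with a larger error (SE 0.30; limma adjusted p = 0.0110). Further falls were those of the actin-binding Coro2b (-1.47), the Nodal pathway factor Foxh1 (-1.38), Nexmif (-1.27), the histone variant Macroh2a2 (-1.23), the channel Pkd2l1 (-1.21) and Radx (-1.14).

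In all, 2840 genes were called in TS cells, 1317 higher and 1523 lower (limma, adjusted p under 0.05), of which 25 rose and 16 fell by at least 2-fold. The count was 1789 without TS control replicate 1, and 259 genes passed limma's treat against a 1.2-fold minimum.

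Mitosis genes were lower in 18 of 19 cases and higher in 0 (19 lower adjusted over the list alone). The list median was -0.24 (camera adjusted p = 5.46e-13; adjusted p = 0.191 with an estimated correlation). The spindle checkpoint genes Bub1b and Bub1 fell by 0.41 and 0.39, Cenpf by 0.38 and Cdc20 by 0.31. DNA replication genes were lower in 15 of 18 cases and higher in 0 (16 lower adjusted over the list alone). The median was -0.28 (camera adjusted p = 9.53e-11; adjusted p = 0.191 with an estimated correlation). Cdc6, a licensing factor, fell by 0.44, Pola1 by 0.40, and the helicase subunits Mcm4 and Mcm3 by 0.39 and 0.35. Cholesterol synthesis genes were lower in 9 of 14 cases and higher in 0 (10 lower adjusted over the list alone). The median was -0.18 (camera adjusted p = 9.17e-06; adjusted p = 0.191 with an estimated correlation). Msmo1 fell by 0.36, Pmvk by 0.34 and Cyp51 by 0.29.

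Of 15 genes in the FGF-ERK feedback and targets list, 8 were lower and 2 higher (8 and 3 adjusted over the list alone). The list median was -0.22 (camera adjusted p = 0.00504; adjusted p = 0.247 with an estimated correlation). The feedback inhibitors Spry1 and Spry4 fell by 0.97 and 0.64 and the transcription factor Etv5 by 0.67, while Fos rose by 0.46. Trophoblast stem cell genes were lower in 7 of 14 cases and higher in 3 (7 and 4 adjusted over the list alone). The median was -0.20 (camera adjusted p = 0.0357; adjusted p = 0.574 with an estimated correlation). The call of this list was lost in 6 of 11 alternatives (adjusted p from 0.0252 to 0.0925). Elf5 fell by 0.44 (limma adjusted p = 0.0133), a call lost without TS control replicate 1 or TS Tet replicate 3, and Bmp4 fell by 0.30, while Tfap2c (0.13, limma adjusted p = 0.145) and the FGF receptor Fgfr2 (10.99 ± 0.06 and 10.99 ± 0.11) did not pass the test. In the DNA methylation and Polycomb list, 7 of 16 members were lower and 2 higher (8 and 2 adjusted over the list alone). Its median was -0.13 (camera adjusted p = 0.00842; adjusted p = 0.574 with an estimated correlation). Jarid2, a Polycomb cofactor, fell by 0.53, Dnmt3l by 0.38 and Uhrf1 by 0.35.

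Trophectoderm and early trophoblast epithelium genes were higher in 10 of 15 cases and lower in 0 (11 higher adjusted over the list alone). The list median was 0.30 (camera adjusted p = 9.53e-11; adjusted p = 0.0826 with an estimated correlation). Gata2 rose by 0.67, Krt18 by 0.64, Dlx3 by 0.62 and Krt19 by 0.52. Of the spongiotrophoblast and syncytiotrophoblast list, 5 of 14 members were higher and 1 lower (6 and 1 adjusted over the list alone). The median was 0.15 (camera adjusted p = 0.00136; adjusted p = 0.0826 with an estimated correlation). Nrk, Gjb2 (1.15) and Flt1 (1.15) had the largest rises. Interferon response genes were higher in 4 of 11 cases and lower in 0 (5 higher adjusted over the list alone). The median was 0.21 (camera adjusted p = 0.00112; adjusted p = 0.247 with an estimated correlation). Gbp2, Rsad2 (1.14) and Usp18 (1.00) led these rises. Epithelial junction genes went both ways, with 8 of 15 higher and 2 lower, adjusted over the list alone as well, and a median of 0.20 (camera adjusted p = 0.0213; adjusted p = 0.589 with an estimated correlation). Pkp2 and Dsg2 of the desmosome rose by 0.47 and 0.39, and the tight junction gene Ocln fell by 0.62. Without TS Tet replicate 2 this list call was lost (adjusted p = 0.0738).

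The other 14 lists did not pass the camera test in TS cells. Pluripotency genes had 2 members higher and 5 lower of 28 (median -0.07, camera adjusted p = 0.102; past the test in 2 of 11 alternatives, down to 0.0296). Stress and immediate early genes had 4 higher and 0 lower of 14 (median 0.11, camera adjusted p = 0.0596; past the test in 4 of 11, down to 0.0233). Fibroblast markers had 2 higher and 0 lower of 23 (median 0.04, camera adjusted p = 0.105; past the test in 3 of 11 alternatives, with adjusted p down to 0.0214). Targets of p53 had 1 higher and 0 lower of 16 (camera adjusted p = 0.139; 0.0319 after cyclic loess) and primitive endoderm genes 4 higher and 2 lower of 19 (median 0.04, camera adjusted p = 0.142). Within that last list Col4a2 and Col4a1 rose by 0.58 and 0.53 and Gata4 fell by 0.47. Glycolysis and hypoxia genes had 3 higher and 4 lower of 16 (camera adjusted p = 0.287), with Pdk1 at -0.66, and imprinted genes 1 higher and 3 lower of 17 (camera adjusted p = 0.605). None of the 13 trophoblast giant cell genes was called (median 0.05, camera adjusted p = 0.783; largest value Cts7 at 0.28, limma adjusted p = 0.101). Mesendoderm genes had 1 higher and 3 lower of 16 (median 0.07, camera adjusted p = 0.900). Other Sox genes had 0 higher and 3 lower of 18 (median 0.01, mean -0.03, camera adjusted p = 0.456), and BMP-SMAD targets 2 higher and 1 lower of 12 (median -0.02, mean 0.02, camera adjusted p = 0.893). Neuroectoderm genes had 1 higher and 1 lower of 14 (median 0.03, mean -0.00, camera adjusted p = 0.893), and germline genes 1 higher, Taf7l, and 1 lower of 14 (median -0.06, mean 0.05, camera adjusted p = 0.900). Postimplantation epiblast genes had 1 higher and 1 lower of 11 (median 0.01, mean -0.03, camera adjusted p = 0.946). In these last 5 lists the median, the mean and the camera test differed in sign.

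**Figure D2:**
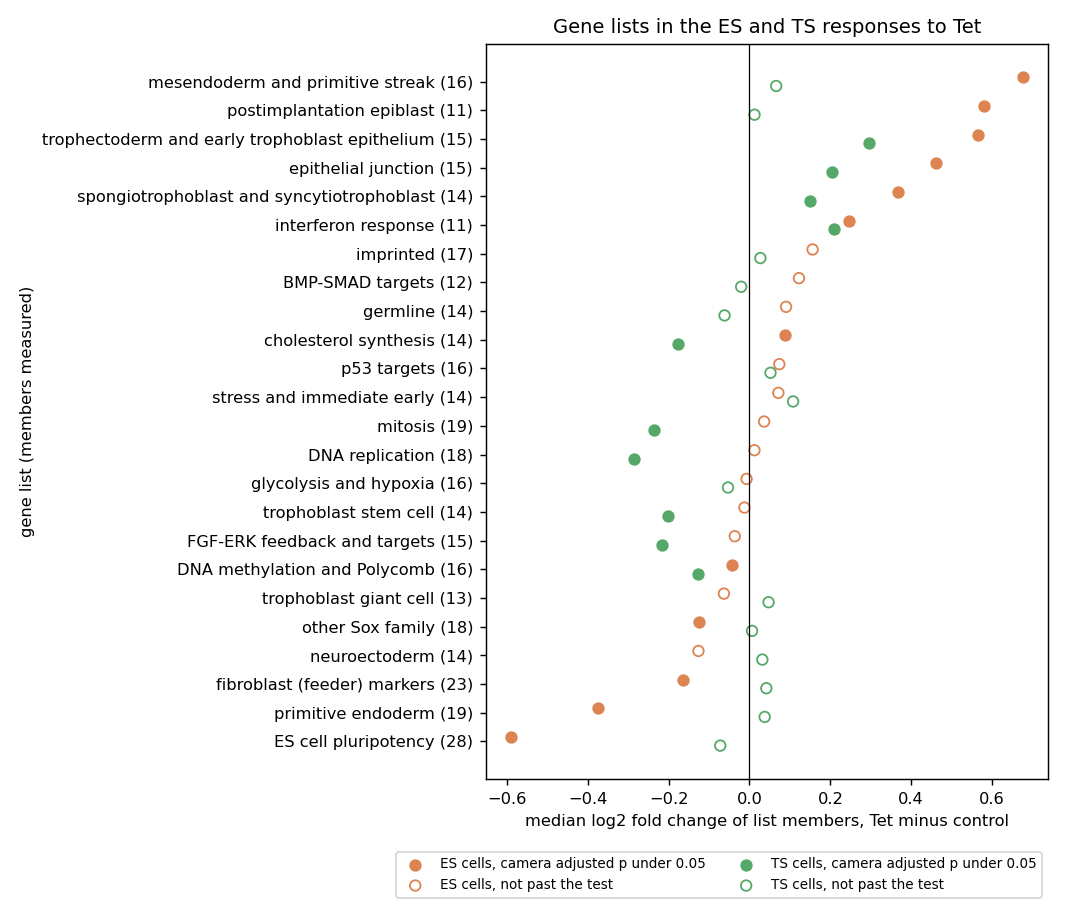
Median log2 fold change (x axis, Tet minus control) of the measured members of 24 gene lists (y axis, number measured in parentheses) in the ES arrays labelled Tet (orange) and in TS cells (green). Filled points passed limma's camera test at the preset correlation. Pluripotency genes had the lowest median in ES cells (-0.59) and DNA replication genes the lowest in TS cells (-0.28).

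The third comparison tested, as an interaction, which genes responded differently in the TS and ES lines, given as the TS change minus the ES change. The highest differences belonged to genes that fell in the ES arrays labelled Tet and fell less, did not pass the test or rose in TS cells. They were Necab1 (3.07 ± 0.11 SE), Nr5a2 (2.29 ± 0.10), the lipase gene Liph (2.22 ± 0.09), Susd2 (1.96 ± 0.11), Tbx3 (1.95 ± 0.08) and Lix1 (1.90 ± 0.11). In untreated TS cells Necab1 read 6.20 and Nr5a2 6.23, against 9.32 and 9.82 in untreated ES cells. Both thus started in TS cells at about the level to which Necab1 fell in the ES arrays labelled Tet. Their differences may reflect little room to fall in TS cells rather than an unlike response to Tet. Of the others, Lix1 fell in TS cells as well (-0.83), whereas Liph (0.72), Susd2 (0.45) and Tbx3 (0.45) rose there. Mrgpra9 (1.99 ± 0.37) and Serpina3i (1.85 ± 0.35) had larger errors. Cpm rose by 1.00 in ES cells and fell by 1.94 in TS cells, a difference of -2.93 ± 0.06, and Tm6sf1 had a difference of -2.18 ± 0.14. Cyp26a1 (-2.81 ± 0.08), Aplnr (-2.17 ± 0.10), Klhl4 (-2.07 ± 0.14), Bmp5 (-1.98 ± 0.21), Cer1 (-1.84 ± 0.17) and Pkd1l1 (-1.77 ± 0.13) rose in the ES arrays labelled Tet. In TS cells Cyp26a1 fell by 0.63 and the other 5 did not pass the test. The interaction had a limma adjusted p of 0.00394 or lower for all 16 genes.

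Among the stem cell regulators, Sox21 (difference 0.87) and Bmp4 (0.59) fell in both lines and further in ES cells. Klf4 (1.19), Sox15 (0.60) and Fgf4 (0.59) were called lower in ES cells and did not pass the test in TS cells, the reverse held for Cdx2 (-0.65), and Eomes (-1.22) rose in ES cells and fell in TS cells. Gata3 (-0.51) rose in ES cells and did not pass the test in TS cells, and the Sox2 probe set gave -0.82 ± 0.17 (limma adjusted p = 0.00677). For Nanog (0.22, limma adjusted p = 0.306), Pou5f1 (0.37, limma adjusted p = 0.106), Esrrb (0.13, limma adjusted p = 0.347), Elf5 (-0.42, limma adjusted p = 0.0560) and Fgfr2 (0.25, limma adjusted p = 0.0725) the difference between the lines did not pass the test. In all, 4411 genes were called, 1724 with a positive and 2687 with a negative difference (limma), of which 85 and 114 differed by at least 2-fold. With arrays centred on their medians the split was 3256 positive and 1992 negative (103 and 87 by at least 2-fold), and over all probe sets 119 positive and 404 negative differences were at least 2-fold. In the gene fit, 711 genes passed limma's treat against a 1.2-fold minimum.

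Of the 24 lists, 9 differed between the lines by camera. Primitive endoderm genes had 12 of 19 positive and 3 negative differences (median 0.42, camera adjusted p = 2.32e-07; adjusted p = 0.0415 with an estimated correlation; 13 and 3 adjusted over the list alone). Mesendoderm genes had 0 positive and 10 negative of 16, adjusted over the list alone as well (median -0.49, camera adjusted p = 8.49e-07; adjusted p = 0.0415 with an estimated correlation). The pluripotency list had 16 positive and 4 negative of 28, adjusted over the list alone as well (median 0.47, camera adjusted p = 7.56e-07; adjusted p = 0.182 with an estimated correlation). Mitosis genes had 0 positive and 14 negative of 19 (16 negative adjusted over the list alone; median -0.27, camera adjusted p = 7.56e-07; adjusted p = 0.347 with an estimated correlation). DNA replication genes had 0 positive and 11 negative of 18 (15 negative adjusted over the list alone; median -0.27, camera adjusted p = 1.33e-05; adjusted p = 0.347 with an estimated correlation). Cholesterol synthesis genes, of which Msmo1, Cyp51 and Hmgcs1 rose in ES cells and fell in TS cells, had 0 positive and 10 negative of 14 (11 negative adjusted over the list alone; median -0.31, camera adjusted p = 1.85e-05; adjusted p = 0.184 with an estimated correlation). Epithelial junction genes had 2 positive and 11 negative of 15, adjusted over the list alone as well (median -0.48, camera adjusted p = 4.81e-05; adjusted p = 0.347 with an estimated correlation). Fibroblast markers had 11 positive and 0 negative of 23 (12 and 1 adjusted over the list alone; median 0.19, camera adjusted p = 0.000204; adjusted p = 0.414 with an estimated correlation). Postimplantation epiblast genes had 1 positive and 6 negative of 11 (2 and 6 adjusted over the list alone; median -0.48, camera adjusted p = 0.0148; adjusted p = 0.182 with an estimated correlation). The call of the postimplantation list was lost when the dimmest 30% of genes were left out (adjusted p = 0.0601). Before Tet, 27 of 28 pluripotency genes were already lower in TS than in ES cells and 0 higher. Of 19 primitive endoderm genes, 12 were lower and 4 higher. Low starting levels may have left such genes less room to fall in TS cells, which was not tested. For the trophectoderm (median -0.18, camera adjusted p = 0.564), spongiotrophoblast and syncytiotrophoblast (-0.16, camera adjusted p = 0.159), trophoblast stem cell (-0.13, camera adjusted p = 0.918), interferon (-0.05, camera adjusted p = 0.847) and FGF-ERK (-0.01, camera adjusted p = 0.791) lists, no difference between the lines passed the test. The same held for the other Sox (0.10, camera adjusted p = 0.152; 0.0449 without the dimmest 30% of genes), imprinted (-0.05, camera adjusted p = 0.474), neuroectoderm (0.19, camera adjusted p = 0.554) and p53 (-0.05, camera adjusted p = 0.791) lists. No difference passed for the giant cell (0.00, camera adjusted p = 0.943), BMP-SMAD (-0.07, camera adjusted p = 0.998) and glycolysis (-0.02, camera adjusted p = 0.998) lists. Neither did any difference pass for the germline (median -0.12, mean 0.08, camera adjusted p = 0.998), DNA methylation (median -0.01, mean 0.07, camera adjusted p = 0.918) and stress (median -0.00, mean 0.01, camera adjusted p = 0.998) lists, whose medians and means differed in sign.

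The calls of the 2 responses, which share no arrays, were also compared. Both came from 1 fit with a shared estimate of each gene's spread, so a gene of low spread is more readily called in both. The counts for independent lists below are therefore only a rough guide. Genes called in both numbered 1415, of which 903 moved the same way and 512 opposite ways. Higher in both were 633 genes, against 251.9 for independent lists of these sizes, and lower in both were 270, against 188.3. Higher in ES and lower in TS cells were 355, against 291.3, and the reverse held for 157, against 162.9. Across all 17418 genes, which are not independent replicates, the log2 fold changes of the 2 responses had a Pearson correlation of 0.0859 and a Spearman correlation of -0.0234. A change of at least 2-fold in the same direction was called in both lines for 14 genes and in opposite directions for 0. Higher in both were Gjb2, Gpr50, Nrk, Plac1, Flt1, Zfp36l3, Serpinb9c, Gbp2, Rsad2, Dnase1l3 and 4932442L08Rik, and lower in both were Ildr1, Nexmif and St8sia1. Flt1 rose by 1.28 in ES and 1.15 in TS cells and Nrk by 1.44 and 1.36, and Ildr1, of tricellular junctions, changed by -1.29 and -1.13. The ganglioside-forming sialyltransferase St8sia1 changed by -1.24 and -1.09.

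**Figure D3:**
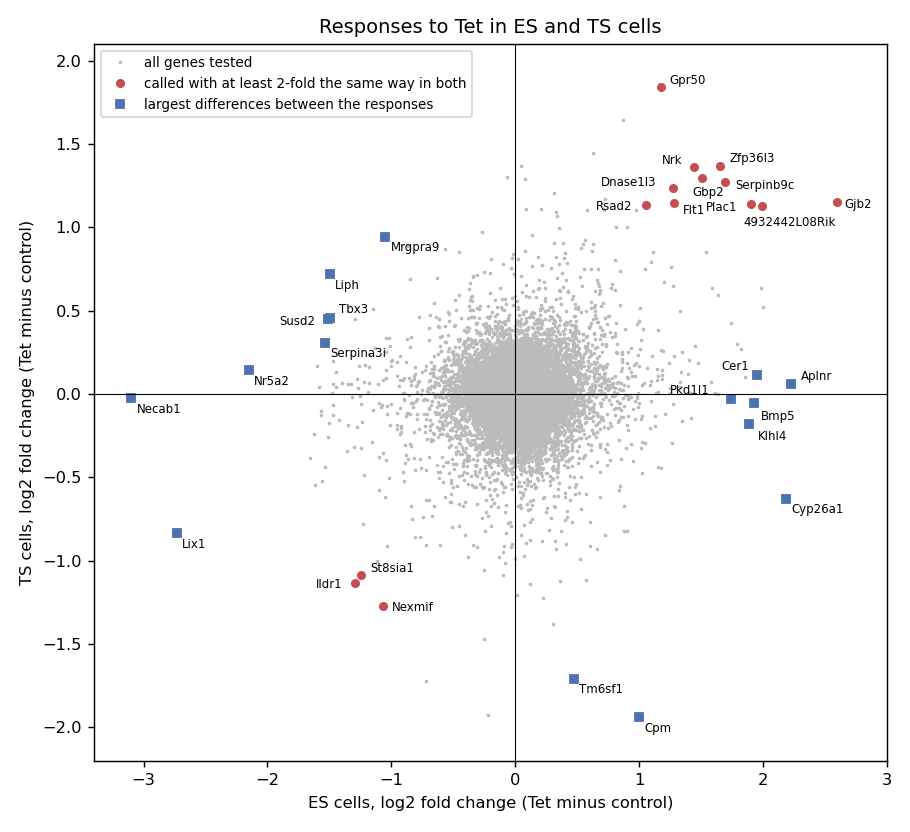
Log2 fold changes (Tet minus control) of all 17418 genes in ES cells (x axis) and TS cells (y axis). Red points are the 14 genes called with at least a 2-fold change the same way in both lines, and blue squares are the named genes with the largest differences between the responses, such as Necab1 and Cpm.

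The last comparison set untreated TS cells against untreated ES cells, which differ in medium as well as in cell type. ES cells had far higher levels of the pluripotency genes Tdgf1, a Nodal co-receptor (75.4-fold; -6.24 ± 0.11 SE in TS minus ES), Nr0b1 (-5.60 ± 0.11) and Nanog (38.8-fold; -5.28 ± 0.11), and of the thyrotropin-releasing hormone gene Trh (-6.05 ± 0.14). TS cells had higher levels of Bmp8b (13.8-fold; 3.79 ± 0.07), Morc4 (3.59 ± 0.06), Acpp (3.54 ± 0.07) and the trophoblast factor Elf5 (9.84-fold; 3.30 ± 0.10). Background was not judged for single probe sets, so folds against low levels, such as Nr0b1 in TS cells (6.39) and Elf5 in ES cells (6.97), are minimum values if these levels are background. Each of these 8 genes had a limma adjusted p of 7.76e-10 or lower. The regulators Gata3 (2.08), Tfap2c (1.62), Cdx2 (1.52), Fgfr2 (0.99) and Eomes (0.82) were higher in TS cells. Mmp9 (2.91), Vnn1 (2.79), Cited1 (2.78) and the homeobox gene Hoxc9 (2.73) were also higher in TS cells, and Fbxo15 (-4.81), Slc7a3 (-4.60), Srgn (-4.55) and Otx2 (-4.53) were lower. The Sox2 probe set read 2.29-fold lower in TS cells (-1.19 ± 0.12, limma adjusted p = 9.47e-06). Sox2ot was lower as well, by 2.29 on the log2 scale, and which transcripts of the locus the Sox2 probe set reads is not known here. Pou5f1 (-4.32) and Fgf4 (9.64-fold) were lower too. Sox21 (-0.75) and Sox3 (-0.37) were lower as well, while Sox15 (-0.03, limma adjusted p = 0.816) did not pass the test.

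In all, 9096 genes were called between the untreated lines, 4048 higher and 5048 lower in TS cells (limma, adjusted p under 0.05), and 316 were higher and 535 lower by at least 2-fold. Centred on array medians, 5159 were higher and 3965 lower. Over all probe sets the 2-fold balance turned, with 820 higher and 663 lower. In the gene fit, 3581 genes passed limma's treat against a 1.2-fold minimum.

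By camera, 15 of 24 lists were called, 5 higher and 10 lower in TS cells, and 0 of them with an estimated correlation. Pluripotency genes were lower in 27 of 28 cases, adjusted over the list alone as well (median -1.69, camera adjusted p = 1.92e-16; adjusted p = 0.0516 with an estimated correlation). Epithelial junction genes were higher in 15 of 15 cases, adjusted over the list alone as well (median 1.05, camera adjusted p = 1.70e-11; adjusted p = 0.108 with an estimated correlation), with Dsc2 at 2.63, Dsp at 2.22 and Cldn3 at 1.94. The trophectoderm list had 10 higher and 4 lower of 15, adjusted over the list alone as well (median 1.06, camera adjusted p = 0.000554; adjusted p = 0.226 with an estimated correlation), with Krt18 at 2.55 and Hand1 at 2.27. The trophoblast stem cell list had 8 higher and 5 lower of 14, adjusted over the list alone as well (median 0.71, camera adjusted p = 0.0448; adjusted p = 0.418 with an estimated correlation), the lower members being Esrrb, Bmp4, Satb1, Spry4 and Sox21. That call was lost in 5 of 11 alternatives (adjusted p up to 0.122). The spongiotrophoblast and syncytiotrophoblast list had 8 higher and 1 lower of 14 (median 0.33, camera adjusted p = 0.0121; adjusted p = 0.108 with an estimated correlation; adjusted p = 0.0585 without the dimmest 30% of genes; same counts adjusted over the list alone). Targets of p53 had 10 higher and 3 lower of 16 (median 0.27, camera adjusted p = 0.00165; adjusted p = 0.229 with an estimated correlation; 11 higher adjusted over the list alone), with Perp at 1.05 and Polk at 0.92.

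Lower in TS cells were DNA replication genes (17 of 18 lower and 1 higher, median -0.60, camera adjusted p = 1.63e-06; adjusted p = 0.236 with an estimated correlation). Mitosis genes were lower as well (15 of 19 lower and 1 higher, median -0.26, camera adjusted p = 0.00183; adjusted p = 0.418 with an estimated correlation). DNA methylation and Polycomb genes were lower in 11 of 16 cases and higher in 1 (median -0.59, camera adjusted p = 0.000554; adjusted p = 0.250 with an estimated correlation), with Dnmt3l at -3.71 and Tet2 at -1.95. Postimplantation epiblast genes were lower in 9 of 11 cases and higher in 2 (median -0.99, camera adjusted p = 0.000603; adjusted p = 0.0849 with an estimated correlation), led by Otx2 and Fgf5 (-3.73). Primitive endoderm genes were lower in 12 of 19 cases and higher in 4 (median -0.38, camera adjusted p = 0.0120; adjusted p = 0.226 with an estimated correlation), led by Cubn (-4.36) and Lama1 (-3.33). Germline genes were lower in 8 of 14 cases and higher in 2 (median -0.37, camera adjusted p = 0.0121; adjusted p = 0.108 with an estimated correlation), led by Sycp3 (-3.39). Mesendoderm genes were lower in 11 of 16 cases and higher in 2 (median -0.45, camera adjusted p = 0.0143; adjusted p = 0.226 with an estimated correlation). FGF-ERK genes were lower in 10 of 15 cases and higher in 3 (median -0.27, camera adjusted p = 0.0214; adjusted p = 0.278 with an estimated correlation), with Spry2 at -1.69 and Etv5 at -1.52. Fibroblast markers were lower in 15 of 23 cases and higher in 4 (median -0.34, camera adjusted p = 0.0448; adjusted p = 0.544 with an estimated correlation), a call lost in 5 of 11 alternatives (adjusted p up to 0.0620). Col6a1 (-0.87) and Col3a1 (-0.75) were lower and Tagln (0.86) higher. Adjusted over each list alone, the counts of these 9 lists were the same except for 10 lower germline genes and 11 lower FGF-ERK genes. Not called were 9 lists, among them the trophoblast giant cell (median 0.23, camera adjusted p = 0.124), neuroectoderm (-0.17, camera adjusted p = 0.105) and other Sox (-0.20, camera adjusted p = 0.0933) lists. The stress (0.03, camera adjusted p = 0.128), cholesterol (0.12, camera adjusted p = 0.174) and glycolysis (-0.16, camera adjusted p = 0.561) lists did not pass either, nor did the BMP-SMAD (-0.10, mean 0.24, camera adjusted p = 0.569), imprinted (-0.09, camera adjusted p = 0.621) and interferon (-0.20, camera adjusted p = 0.979) lists. For the last 3 the camera test was positive and the median negative.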

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

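The tests that regrouped the arrays were written down before their values were seen, and all other tests here were chosen after the result was seen. For the 2 Tet responses and the untreated lines, whether chance alone could give such counts was not settled: among 10 splits of 6 arrays into 3 and 3, the real labels alone gave calls (5485 in ES cells, 2840 in TS cells and 9096 between the untreated lines, against 0 in every other split). A share of 1 in 10 splits is too large for a test at 0.05. For the difference between the lines, 100 labellings were counted, the real one among them, and only the real one reached 4411 genes. The highest other, which kept the ES labels as they were, reached 2384. Such relabelling breaks up the response of each line, so it tests against no effect of Tet in either line. It cannot tell differing responses from equal ones, so chance was not settled for the difference either.

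The Sox2 probe set was not lower in the ES arrays labelled Tet (0.31, limma adjusted p = 0.0809). Swapped ES labels were argued against by the pluripotency list, whose median was -0.59 in the labelled direction, although this takes for granted that loss of Sox2 lowers pluripotency genes. Sox2ot, which overlaps Sox2, changed by 0.53 in the same arrays, which is in line with a probe set that reads transcripts of the locus that Tet does not remove. The probe positions and the construct are not given in the sources used here, so this stayed open.

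Pluripotency genes and fibroblast markers were both lower in the ES arrays labelled Tet. A trend with signal was argued against by cyclic loess, after which the fibroblast list still had a median of -0.24. A changed share of feeder cells alone was argued against by the mesendoderm list, whose median was 0.68 beside -0.59 for pluripotency, since a share would move both lists of the ES lineage the same way. A smaller feeder share could still lie behind the fibroblast list, where 2 called members were higher, and this was not settled.

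The 4411 genes with differing responses were led by Necab1 (3.07), Nr5a2 (2.29), Liph (2.22), Mrgpra9 (1.99), Susd2 (1.96), Tbx3 (1.95), Lix1 (1.90) and Serpina3i (1.85), and by Cpm (-2.93), Cyp26a1 (-2.81), Tm6sf1 (-2.18), Aplnr (-2.17), Klhl4 (-2.07), Bmp5 (-1.98), Cer1 (-1.84) and Pkd1l1 (-1.77). Among the panel, Sox2 (-0.82), Klf4 (1.19), Cdx2 (-0.65), Eomes (-1.22), Fgf4 (0.59), Bmp4 (0.59), Gata3 (-0.51), Sox15 (0.60) and Sox21 (0.87) differed. List medians of the difference were 0.47 for pluripotency, 0.42 for primitive endoderm, -0.49 for mesendoderm and primitive streak, -0.48 for postimplantation epiblast, -0.27 for mitosis, -0.27 for DNA replication, 0.19 for fibroblast markers, -0.48 for epithelial junction and -0.31 for cholesterol synthesis. Medium and cell type differ together between the lines, so neither could be held responsible. Low starting levels in TS cells, as for Necab1 and Nr5a2, may also limit a fall there, which was not tested.

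Probe sets without a single gene symbol were left out of the gene tests. Of these 10660, 191 were called with at least a 2-fold change in ES cells, 171 higher and 20 lower (1.79%, against 0.952% of single-symbol probe sets in the same fit of all probe sets), and 18 in TS cells, 8 higher and 10 lower (0.169%, against 0.235%). Those with a 2-fold change were dim, with a median signal of 5.73 (log2) for ES cells and 5.43 for TS cells, below the array medians of 7.71 to 7.82. The ES balance over all probe sets given above thus rests partly on dim probe sets. What these probe sets read was not examined here.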

How the results depend on the processing

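The alternatives were planned before the values were seen, except cyclic loess, the list tests under other scalings and some settings for shared calls, which were chosen after the result was seen. No alternative turned the sign of a named gene's called change or of the median of a called list, but the share of called ES genes that were higher went from 60.7% to 36.2% with median centring. With an estimated correlation, camera called 4 lists in ES cells, 0 in TS cells, 2 for the difference and 0 between untreated lines, while fry called 24 for the last. Sox2 in ES cells passed the test without the dimmest 30% of genes (0.31, adjusted p = 0.0446), with array weights (0.36, adjusted p = 0.0230) and without ES Tet replicate 3 (0.41, adjusted p = 0.0373); without ES Tet replicate 2 it was 0.25 (adjusted p = 0.210). Sox2 in TS cells ranged from -0.64 without TS Tet replicate 3 to -0.42 without TS Tet replicate 2. Calls in TS cells numbered 1789 without TS control replicate 1 and 2488 without TS Tet replicate 2, against 2840, where fewer arrays leave fewer degrees of freedom. By construction treat calls fewer genes, with 831 (ES), 259 (TS), 711 (difference) and 3581 (untreated), and Sox2 in TS cells (-0.51) did not pass it. With the replicate number as a block within each line, 3618, 1227 and 2342 genes were called, and Sox2 in TS cells was -0.51 (adjusted p = 0.0879). Replicates of the same number correlated at -0.153 to 0.124 after group means were removed, others at -0.138 to 0.180, so the numbers do not mark pairs. The cause of the other changes was not tested.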

Other observations

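Apart from the planned responses and gene lists, the tests in this part were chosen after the result was seen. In the ES arrays labelled Tet, the fall of Klf4, Nr5a2 and Tbx3 with the rise of Fgf5, Mixl1 and Lhx1 might reflect an exit from naive pluripotency, which staining of single cells would test. Pooled RNA cannot show which cells changed, and trophoblast genes went both ways. Krt18 and Krt19 rose, Tfap2a (-1.13) and Dab2 (-0.69) fell, and the trophoblast stem cell list was not called (camera adjusted p = 0.459). Of all 43 genes with the symbol root Krt, which were not chosen as trophoblast genes, 11 were lower and 3 higher. The call of that family (camera adjusted p = 0.017) was lost after cyclic loess (camera adjusted p = 0.571). These directions rest on the Tet label, which the Sox2 probe set could not check. Across genes, the ES response and the difference of untreated TS from ES cells had a covariance of 0.0450. Replicate noise in the shared ES control arrays alone gave a simulated mean of 0.00581 and at most 0.00635, so it is an unlikely source of the whole covariance. The correlation was 0.337, and shared noise alone gave a simulated mean of 0.502 and at most 0.534. These cannot be set against each other, since the simulated groups held no real changes, which alter a correlation. The correlation therefore counts neither for nor against a shared profile. Called genes higher in both numbered 1769 against 774.1 for independent lists, and those lower in both 1273 against 624.3. These lists share the ES control arrays and the estimate of each gene's spread, so they are not independent.

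In TS cells, the fall of Cdx2, Eomes, Esrrb, Spry1 and Etv5 with mitosis and DNA replication genes and the rise of Nrk, Flt1, Gjb2 and Dlx3 is consistent with reduced self-renewal and a start of differentiation, which counts of dividing cells and staining would test. Against this, Nrk, Flt1 and Gjb2 rose at least 2-fold in ES cells too and Dlx3 by 0.80, so they are no markers of TS differentiation alone and a direct effect of Tet stays open. Ets2 (0.36), Tead4 (0.28) and Satb1 (0.25) of the trophoblast stem cell list rose, and the call of that list was lost in 6 of 11 alternatives. Of 14 spongiotrophoblast and syncytiotrophoblast genes, 5 were higher and 1, Slc16a1 (-0.27), was lower. The other 8 did not pass the test, among them Tpbpa (0.10) and Prl8a8 (0.14). Of the 20 giant cell genes on the list, 13 were measured and none was called at 4 days. The mean signal of these 13 was below the array medians of 7.71 to 7.82 (log2) in every array. A change in dim or unmeasured genes could be missed, so the lack of calls says little for or against giant cell differentiation. The mitosis and DNA replication list calls did not hold in camera with an estimated correlation, where 0 TS lists were called, so co-regulation of their members, which passed the test singly in 18 of 19 and 15 of 18 cases, leaves the list p-values uncertain. RNA levels alone do not show that proliferation changed.

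The 14 genes that moved 2-fold the same way in both lines are candidates for common effects of Sox2 loss. Of these, 13 or more kept the 2-fold change under quantile normalization, median centring or cyclic loess. The deposited arrays had close medians, so these rescalings could hardly move genes chosen for 2-fold changes. They also start from processed values, so they cannot test the original normalization. A direct effect of Tet could not be told apart, since the 14 genes were not measured in Tet-treated cells without the inducible knockout. Gbp2 and Rsad2 are interferon response genes, and the interferon list was called higher in both lines, with 5 of 11 members higher in ES and 4 of 11 in TS cells. Neither list call held with an estimated correlation (adjusted p = 0.372 and 0.247), and Ddx58 fell in ES cells.

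Families of genes sharing a symbol root, 280 in all, were tested with camera; 20 were called in the TS response and 6 in the ES response, none of which held with an estimated correlation (adjusted p = 0.269 or higher). Of 9 Hox C genes, 8 were lower in TS cells with Tet, with a median of -0.48 (camera adjusted p = 1.13e-06; 0.269 with an estimated correlation), among them Hoxc10 (-0.95), Hoxc9 (-0.90) and Hoxc5 (-0.77), while Hoxc11 (-0.74, limma adjusted p = 0.124) did not pass the test. All 9 were higher in untreated TS than ES cells (median 1.40). A signal trend is unlikely to explain the fall, since the median after cyclic loess was -0.48. The difference of the Hox C response between the lines, with a median of -0.45, 3 members lower and 1 higher, did not pass the test (camera adjusted p = 0.0692), which leaves a difference open.

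Further tests would be Sox2 protein in the ES cultures, Tet treatment of a line without the inducible knockout, arrays of feeders alone and counts of dividing cells in TS cultures.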
